A study of Mus musculus with 5 samples.

How the data were processed

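RNA of mouse NT2.5 mammary tumour cells and of sub-lines derived from them was measured on 5 Affymetrix mouse expression arrays of 1 colour. Per the labels' protocols, total RNA was purified on RNeasy columns and 5 ug of it went into biotin-labelled cRNA. Per the labels, 1 array each held the parental cells, the bone sub-line at passages 3 and 6, and the liver sub-line at passages 1 and 3. The authors deposited 1 intensity per probe set, on a linear scale, for 45101 probe sets. The submitters' processing notes name RMA, whose version is not given in the sources used here. The intensities do not have the log2 scale that RMA gives. Their mean after trimming 2% at each end was 150 on each of the 5 arrays, which is what a global scaling to a fixed target leaves. Which further steps were applied is not given in the sources used here.

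The tests had been planned for log2 values, so the intensities were first converted to log2(intensity + 16), with no further normalization. A fold change is on this scale and understates the change of dim genes. Gene names came from the platform annotation, which listed 35890 of the 45101 probe sets. Of these, 34945 had 1 gene and 932 had several, and 9211 probe sets were not listed. The symbols of 34741 probe sets were matched by gene identifier to a RefSeq table of assembly GRCm38.p6, which was used for names only, and 0 symbols changed. Probe sets with several genes or none and the 64 control probe sets were left out. A probe set was kept where its highest intensity of the 5 arrays was at or above the median of all values, 25.1. The probe set with the highest mean stood for its gene, which left 12609 of 18193 genes to test. Several probe sets were present for 9010 genes.

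Genes were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 over all 5 arrays, with 3 lines (parental, bone and liver) as groups and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. No passage was measured more than once, so the passages of a sub-line stood in for replicates, and the lone parental array was assumed to vary as the passages do. The p-values measure only the spread between these samples, which are successive passages of 1 lineage each and may differ technically, and they say nothing of other bone or liver isolates. The fit had 2 residual degrees of freedom and a prior of 4.20. Single pairs of arrays have no replicate check: for them, and for final against early passage, only values and counts of genes at least 2-fold apart were computed. The number of arrays limits the precision of every value.

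Before the data were examined, 38 gene lists (pathways, mammary and bone genes, and markers of cell types that cells grown from a tissue could carry along) and the rule for named genes were fixed. For each list with 3 or more tested members, the median log2 difference was placed among those of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these arrays and is not a p-value. Members past the threshold were counted over all genes tested and adjusted over the list alone. The latter does not correct for the number of lists and comparisons, and some genes are on several lists. A member that passed so can be far from the threshold over all genes, as was Cxcl10 for liver against parental (limma adjusted p = 0.557 over all genes). The rule named, per limma comparison and direction, up to 10 called genes with the largest difference of at least 1 on the log2 scale and the same sign in both passages, filled up to 10 with genes at least 2-fold apart in every pair of arrays, given as values. It also named the 5 largest differences in each direction between passages, up to 4 members of each list at least 2-fold apart in every pair, and 16 genes whatever their values. Genes known only by a RIKEN or predicted-gene name were given by count. The rule named 112 genes, of which 46 had several probe sets and 1 had probe sets of opposite sign. Of the genes the rule named, 1 is not reported here. Genes outside the rule are marked as chosen after their values were seen.

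The fit was tested on simulated data, with 200 of the 12609 genes changed in 10 runs. For bone against liver it recovered 0% of 2-fold, 90.5% of 4-fold, 98.7% of 8-fold and 99.3% of 16-fold changes. For bone against parental the shares were 0%, 76%, 95.6% and 99.0%, and for liver against parental 0%, 75.8%, 96.3% and 99.0%. Because both sub-lines were set against the same parental array, unchanged lines against that array were simulated 100 times for the values they share by chance.

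The alternatives set beforehand were no filter, a filter on the mean, median centring, quantile normalization, averaged or all probe sets, a mean-variance trend or robust prior in eBayes, a test against a 1.5-fold change, the stage (early or final) as a block, fits without the other sub-line, each sub-line array left out in turn, and a 3-fold threshold for pairs. Pseudocounts of 1 and 32, a minimum intensity of 100, counts without bone passage 6 or liver passage 1 and list medians without each sub-line array were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.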

Results

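Gene expression was measured in NT2.5 cells, a mammary tumour line from mice that carry the neu oncogene, and in sub-lines of it that prefer bone or liver as the site of metastasis. The parental cells are labelled with a preference for bone, liver and lung. The 5 arrays held 1 sample each, namely parental cells, the bone sub-line at passage 3 (early) and passage 6 (final), and the liver sub-line at passage 1 (early) and passage 3 (final). The median intensity of all probe sets was 26.1 for the parental array, 26.4 and 21.9 for bone passages 3 and 6, and 24.6 and 26.2 for liver passages 1 and 3. The 5'/3' intensity ratio lay between 0.842 and 0.927 for beta-actin and between 1.24 and 1.33 for Gapdh. Across the 12609 genes tested, which are not independent replicates, Pearson's r was 0.979 between the bone passages, 0.973 between the liver passages and 0.953 to 0.967 between arrays of different lines.

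The bone and liver sub-lines were compared to find genes that separate them. Their passage numbers differ (3 and 6 for bone, 1 and 3 for liver) and only passage 3 is shared. The means over passages therefore mix line and passage number. Only the arrays at passage 3, 1 per line, compare the lines at the same passage number. Kank4, which encodes an ankyrin-repeat protein, was 16.8-fold higher in the bone sub-line (log2 difference 4.07 ± 0.37, SE, n = 2 passages per sub-line; limma adjusted p = 0.0437), with intensities of 1097 and 502 at bone passages 3 and 6 and of 24.6 and 34.1 at liver passages 1 and 3. Slc15a3, a lysosomal transporter of peptides and histidine, was 12.7-fold higher (3.67 ± 0.22; adjusted p = 0.0242), and the efflux pump gene Abcg2 was 6.91-fold higher (2.79 ± 0.19; adjusted p = 0.0342). The X-linked homeobox gene Rhox5 was 23.7-fold lower in the bone sub-line (-4.57 ± 0.44; adjusted p = 0.0437), at 63 and 126 against 1662 and 3731 in the liver sub-line and 2810 in parental cells. Prom1, which encodes the membrane glycoprotein CD133, was lower by the same test (-3.93 ± 0.39; adjusted p = 0.0437), as was Clca2, a chloride channel accessory protein (-3.46 ± 0.39; adjusted p = 0.0478).

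In all, 24 genes passed the threshold between bone and liver sub-lines, 12 higher and 12 lower in bone, and 1775 genes had an unadjusted p under 0.05, where chance alone gives 630. The other higher genes included Nqo1, a quinone oxidoreductase and NRF2 target (2.49 ± 0.19), the prolyl isomerase Fkbp11 (2.40 ± 0.26), the tetraspanin Tspan1 (2.40 ± 0.19), the kallikrein Klk10 (2.17 ± 0.22), the biliverdin reductase Blvrb (2.15 ± 0.24), the heparanase homologue Hpse2 (2.03 ± 0.22) and the interleukin receptor subunit Il20rb (1.85 ± 0.20). The other lower genes included Ppm1m (-2.72 ± 0.27), Sel1l3 (-2.70 ± 0.27), the polarity gene Pard3b (-2.47 ± 0.23), the zinc transporter Slc39a8 (-2.21 ± 0.21), the formin Fhod3 (-2.17 ± 0.20) and the secretory-pathway kinase Fam20c (-1.98 ± 0.19). Their limma adjusted p ranged from 0.0342 to 0.0478. A second probe set gave 0.16 for Fkbp11 and 0.73 for Tspan1, and the smallest of 3 for Pard3b was -0.53. Ston2 and Loxl4 (higher) and Veph1 and Pnck (lower), which passed as well, are outside the naming rule and were chosen after their values were seen, and 1 further lower gene has only a RIKEN name. Left out in turn, liver passage 1 and liver passage 3 each brought the limma count from 24 to 0 (1325 and 2020 genes at an unadjusted p under 0.05), whereas it was 75 without bone passage 3 and 53 without bone passage 6. The count was also 0 with no filter (2154 at an unadjusted p under 0.05) and with a pseudocount of 1 (1581), but 161 (75 higher and 86 lower, with all 24 among them) with the early or final stage as a block over the 4 sub-line arrays and 54 with median centring.

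**Figure D1:**
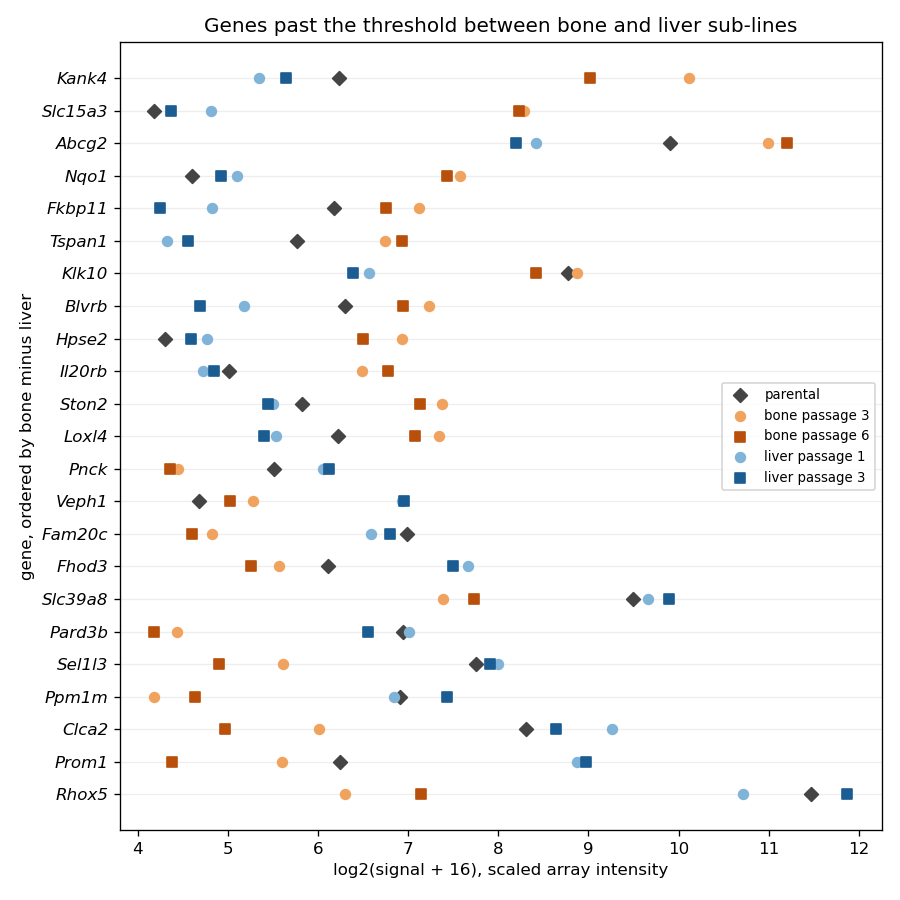
Intensity of genes past the threshold between bone and liver sub-lines, as log2(intensity + 16) on the horizontal axis, with 1 point per array for parental cells, bone passages 3 and 6 and liver passages 1 and 3. Of the 24 genes, 23 are drawn and 1 with only a RIKEN name is left out, and in each of those drawn both bone passages lie on the same side of both liver passages, as for Rhox5 at 63 and 126 against 1662 and 3731.

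Between single arrays, 402 genes were at least 2-fold higher and 323 lower in bone passage 3 than in liver passage 1, and 144 were higher and 441 lower in bone passage 6 than in liver passage 3. After quantile normalization the latter split was 178 higher and 332 lower, so that the share of higher genes went from 24.6% to 34.9%. In every one of the 4 pairs of a bone and a liver array, 134 genes were at least 2-fold apart, 56 higher and 78 lower in bone. These pairs include bone passage 3 against liver passage 3, the passage number that both sub-lines share. The count was 259 without liver passage 1 and 309 without bone passage 6, where 2 pairs remain. Splitting the same 4 arrays by early and final stage gave 7 such genes and the crossed split gave 3. Limma called 0 genes in either, with 340 and 215 at an unadjusted p under 0.05. In both of these splits each group holds a bone and a liver array. The difference between the sub-lines then adds to the spread within groups and lowers the counts, so they do not measure chance.

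Interferon response genes were lower in the bone than in the liver sub-line for 19 of 20 members. Their median log2 difference was -0.90, below all 10000 random lists. Limma called 0 of them over all genes and 0 adjusted over the list alone, with 3 at an unadjusted p under 0.05. The median was -0.21 without bone passage 6 and -1.70 without bone passage 3. Macrophage and monocyte markers were also lower in bone, with a median of -0.86, below all random lists. Of their 15 members, 0 passed over all genes (7 at an unadjusted p under 0.05) and 3 passed adjusted over the list alone. These were Fcgr3 (-1.24 ± 0.20), Csf1r (-0.87 ± 0.21) and Cd68 (-0.86 ± 0.21). The median of the macrophage list was -0.10 without liver passage 1 and -1.36 without liver passage 3. Beside these markers stood antigen presentation genes, with a median of -0.33 (percentile 0.01), which was -0.50 without bone passage 3 and -0.19 without bone passage 6 or without liver passage 3. Over all genes 0 of 16 passed (3 at an unadjusted p under 0.05), and H2-Ab1 (-1.01 ± 0.19) and H2-Aa (-0.82 ± 0.19) passed adjusted over the list alone. Chemokines and their receptors had a median of -0.45, below all random lists, with 0 of 16 past the threshold over all genes (8 at an unadjusted p under 0.05). It was -0.17 without liver passage 1 and -0.35 without bone passage 6. Of the chemokine genes 5 were lower adjusted over the list alone, led by Cxcl10 (-1.76 ± 0.39) and Ccl20 (-1.71 ± 0.37). Members that passed in this way and lie outside the naming rule were chosen after their values were seen.

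NRF2 and glutathione genes were higher in the bone sub-line, with a median of 0.42, above all random lists, and of 0.25 without liver passage 1. Over all genes 1 of 15 members passed, Nqo1. With Gpx2 (1.34 ± 0.27) and Aldh3a1 (0.88 ± 0.22), 3 passed adjusted over the list alone. The 13 luminal mammary genes had a median of 0.33 (percentile 99.8), and 0 passed over all genes (7 at an unadjusted p under 0.05). Among them 4 were higher adjusted over the list alone, with the milk protein gene Csn3 (1.18 ± 0.18) and the transcription factor Gata3 (0.71 ± 0.21). In the same count 2 were lower, Kit (-1.12 ± 0.29) and Csn1s1 (-0.58 ± 0.18). The bone-metastasis signature of breast cancer cells had a median of 0.46 (6 members, percentile 99.5), which was -0.022 without bone passage 3, 0.81 without bone passage 6 and 0.24 without liver passage 3. ERBB receptors and ligands had 0.28 (15 members, percentile 99.8) and oxidative phosphorylation genes 0.27 (23 members, percentile 99.8). In these 3 lists limma called 0 members over all genes and 0 adjusted over the list alone, with 1, 3 and 2 at an unadjusted p under 0.05. Osteoclast-activating factors and their inhibitors, taken as 1 list, had a median of -0.30 (percentile 0.62), or -0.46 without liver passage 3, with 0 of 12 past the threshold over all genes (5 at an unadjusted p under 0.05). Lower when adjusted over the list alone were 2 of them, the macrophage growth factor Csf1 (-1.27 ± 0.21) and the Notch ligand Jag1 (-1.38 ± 0.32). Of the 6 bone matrix genes (median 0.11, percentile 83.5), 0 passed over all genes (2 at an unadjusted p under 0.05). The alkaline phosphatase Alpl (1.63 ± 0.21) and Postn (-1.13 ± 0.34) passed adjusted over the list alone. The bone matrix median was -0.11 without bone passage 3 and -0.063 without liver passage 1, and 0.30 and 0.28 without the other bone and liver passage.

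Further members passed only when adjusted over the list alone. Higher in bone were Cldn8 (1.68 ± 0.33) of the claudins, Id4 (1.43 ± 0.25) of the basal genes, Cd14 (1.45 ± 0.34) of the inflammatory genes, Egln3 (1.84 ± 0.27) of the hypoxia genes and Scd1 (1.40 ± 0.27) of fatty acid synthesis. Lower were Birc3 (-1.75 ± 0.33) of the inflammatory genes and Bnip3 (-1.62 ± 0.35) of the hypoxia genes. Also lower were Pdgfra (-0.97 ± 0.22) of the fibroblast markers, Flt1 (-0.94 ± 0.23) of the endothelial markers and Lpl (-2.71 ± 0.46) of the adipocyte markers. The cell cycle gene Ccnd2 had a difference of 2.14 ± 0.48 and did not pass (limma adjusted p = 0.157). Over all genes, limma called 0 members in 36 of the 37 lists, with 89 of their 482 entries at an unadjusted p under 0.05 (a gene counted once per list). It called 0 in 22 lists adjusted over the list alone as well (36 of 319 entries at an unadjusted p under 0.05).

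The bone sub-line was compared with the parental cells to find genes that set it apart from them. Ecrg4, which encodes a secreted peptide precursor, was 56.2-fold higher (log2 difference 5.81 ± 0.23, SE, n = 2 bone passages and 1 parental array; limma adjusted p = 0.00192), at 6117 and 5801 against 90.3. Sostdc1, a secreted antagonist of BMP and Wnt signalling, was 25.9-fold higher (4.70 ± 0.26; adjusted p = 0.00757). Cytip (4.30 ± 0.42), the secreted semaphorin Sema3b (4.22 ± 0.36), Trim47 (4.11 ± 0.31), Slc15a3 (4.07 ± 0.26), the aspartoacylase Aspa (3.24 ± 0.30), Nqo1 (2.90 ± 0.23) and Crispld2 (2.16 ± 0.22) rose as well, at adjusted p from 0.0146 to 0.0455. The neutrophil chemokine Cxcl5 fell from 1233 to 127 and 112 (-3.21 ± 0.24; adjusted p = 0.0220), and the anti-angiogenic serpin Serpinf1 fell from 1589 to 176 and 221 (-2.91 ± 0.27; adjusted p = 0.0380).

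In all, 17 genes passed between bone sub-line and parental cells, 9 higher and 8 lower, and 1030 had an unadjusted p under 0.05. The other lower genes included Fndc1 (-3.29 ± 0.34), the sodium pump regulator Fxyd6 (-3.24 ± 0.34), the LIM-domain gene Lmo1 (-2.75 ± 0.26), Pard3b (-2.63 ± 0.28) and Fam20c (-2.27 ± 0.24), at adjusted p up to 0.0492. Slc15a3, Nqo1, Pard3b and Fam20c were the 4 genes called against both the liver sub-line and the parental cells. The smallest of 3 probe sets was 0.99 for Cytip, and the other probe set of Fndc1 gave -0.92. Rhox5 (-4.74 ± 0.54; adjusted p = 0.0566), the carboxylesterase Ces1g (-4.07 ± 0.51; adjusted p = 0.0788) and the glutathione transferase Gstp3 (4.16 ± 0.73; adjusted p = 0.153) were 2-fold apart in both passages without passing. The count of 17 was 8 without liver passage 1 and 8 without liver passage 3, 52 without bone passage 3 and 47 without bone passage 6, and Ecrg4, Sostdc1, Slc15a3, Trim47 and Cytip were called in all 4 of these fits. For this comparison the fits without liver passage 1 and without liver passage 3 are the same fit, since a lone liver array adds nothing to the spread. They are not separate checks. With no filter, or with a pseudocount of 1, only 1 gene passed, Ecrg4, and 36 passed with median centring.

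At least 2-fold apart from parental cells were 307 genes higher and 243 lower in bone passage 3, and 185 higher and 400 lower in bone passage 6. For passage 6, quantile normalization gave 227 higher and 311 lower and took the share of higher genes from 31.6% to 42.2%. In both passages 126 genes were higher and 144 lower, 270 in all. Without bone passage 6 the count is that of bone passage 3 alone, 550.

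Hypoxia and glycolysis genes were lower in the bone sub-line than in parental cells for 14 of 19 members (median -0.30, percentile 0.02, and -0.16 without bone passage 6). Over all genes 0 of them passed (5 at an unadjusted p under 0.05), and 4 passed adjusted over the list alone. These were the collagen prolyl hydroxylases P4ha1 (-1.22 ± 0.26) and P4ha2 (-1.11 ± 0.22), Ndrg1 (-1.15 ± 0.23) and the carbonic anhydrase Car9 (-1.14 ± 0.24). The mixed list of osteoclast-activating factors and their inhibitors was lower for 10 of 12 members (median -0.49, percentile 0.01), with 1 past the threshold over all genes, Cxcl5. Adjusted over the list alone 4 passed, with Ccl2 (-1.46 ± 0.26) and Cxcl1 (-1.46 ± 0.35) lower and Tnfrsf11b, the RANKL decoy receptor osteoprotegerin, higher (1.35 ± 0.35). Chemokines had a median of -0.17 (16 members, percentile 12.2), with 1 past the threshold over all genes, Cxcl5. The chemokine median was 0.15 in bone passage 3 and -0.85 in bone passage 6. Of these genes 6 passed adjusted over the list alone, with Ccl20 (-2.32 ± 0.45) and Cxcl12 (-1.31 ± 0.25) lower and Cxcl14 (0.96 ± 0.24) higher. Inflammatory genes had a median of -0.33 (14 members, percentile 0.18), with 0 past the threshold over all genes (4 at an unadjusted p under 0.05). Cxcl1 and Il1a (-1.07 ± 0.26) passed adjusted over the list alone. Antigen presentation genes had a median of 0.15 (16 members, percentile 97.7), or 0.36 without bone passage 6, with 0 past the threshold over all genes (4 at an unadjusted p under 0.05). The immunoproteasome subunits Psmb8 (2.29 ± 0.28) and Psmb9 (1.69 ± 0.38) were higher and H2-Ab1 (-1.05 ± 0.23) was lower adjusted over the list alone.

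Of 13 luminal mammary genes (median 0.08, percentile 77.9, and 0.15 without bone passage 3), 0 passed over all genes (2 at an unadjusted p under 0.05). The oestrogen receptor Esr1 (2.42 ± 0.34, with a lowest probe set of 0.22) and Csn1s1 (-1.96 ± 0.22) passed adjusted over the list alone. Of 12 basal genes (median 0.20, percentile 97.7, with 0.34 in bone passage 3 and 0.074 in bone passage 6), 0 passed over all genes (4 at an unadjusted p under 0.05) and 1 adjusted over the list alone, Id4 (1.61 ± 0.31). The NRF2 list (median 0.04, percentile 71.3, and 0.068 without bone passage 3 or -0.082 without bone passage 6) had Nqo1 past the threshold over all genes and also Aldh3a1 (1.47 ± 0.27) adjusted over the list alone. Wnt10a (2.12 ± 0.44), Scd1 (1.95 ± 0.33), Arg1 (3.59 ± 0.78) and Flt1 (-1.20 ± 0.28) passed only when adjusted over the list alone, in the Wnt, fatty acid, hepatocyte and endothelial lists. Cxcl12 and Pdgfra (-0.98 ± 0.27) did so among the fibroblast markers (8 members, median -0.51, percentile 0.37), whose median was -0.20 without bone passage 6. Collagens and matrix glycoproteins had a median of -0.30 (23 members, percentile 0.07) and claudins 0.38 (10 members, percentile 99.95). The bone-metastasis signature, with 6 of its 11 genes tested, had 0.69 (6 of 6 tested members higher, percentile 99.96). In these 3 lists limma called 0 members over all genes and 0 adjusted over the list alone, with 4, 2 and 1 at an unadjusted p under 0.05. Without bone passage 3 the claudins had 0.17 and the bone-metastasis signature 0.45. Interferon response genes had a median of 0.08 in the mean of the passages, with 0.78 in bone passage 3 and -0.67 in bone passage 6. Macrophage markers had a median of 0.02, with 0.07 in bone passage 3 and -0.05 in bone passage 6. Over all genes, limma called 0 members in 34 of the 37 lists, with 51 of 454 entries at an unadjusted p under 0.05. In 24 lists it called 0 adjusted over the list alone as well (20 of 331 entries at an unadjusted p under 0.05).

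The liver sub-line was compared with the parental cells in the same way. Ecrg4 rose 49.9-fold (log2 difference 5.64 ± 0.23, SE, n = 2 liver passages and 1 parental array; limma adjusted p = 0.00230), to 5663 and 4948 from 90.3, and Sostdc1 rose 12.4-fold (3.63 ± 0.26; adjusted p = 0.0361), to 1133 and 956 from 69.3. These 2 genes were the only ones called, with 945 genes at an unadjusted p under 0.05, and both were also called in the bone sub-line. Without liver passage 1 or without liver passage 3 limma called 0 genes (898 and 1231 at an unadjusted p under 0.05), and without either bone array it called 38. The fits without bone passage 3 and without bone passage 6 are the same fit for this comparison. In both liver passages 108 genes were at least 2-fold higher and 119 lower than in parental cells, 227 in all. Without liver passage 1 the count is that of liver passage 3 alone, 491.

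Among the genes 2-fold apart in both liver passages without passing, the largest values above parental were those of Lgals3bp (4.04 ± 0.47; adjusted p = 0.123), a secreted galectin-3 binding protein, Ankrd1 (3.94 ± 0.99; adjusted p = 0.401), Aspa (3.33 ± 0.30; adjusted p = 0.0814), Clca3a2 (3.27 ± 0.70), Arhgdib (3.25 ± 0.36; adjusted p = 0.106) and Cytip (3.22 ± 0.42). The tight junction gene Cldn2 had 2.84 ± 0.54 and Prom1 2.68 ± 0.47. Values below parental were those of Ces1g (-3.28 ± 0.51), Fndc1 (-3.09 ± 0.34), Dock11 (-3.04 ± 0.49), Fxyd6 (-3.00 ± 0.34), Cxcl5 (-2.92 ± 0.24; adjusted p = 0.0558), the zinc transporter Slc39a4 (-2.82 ± 0.47), Dnm1 (-2.72 ± 0.38, with -0.51 for its other probe set), Gad1 (-2.48 ± 0.59, with -0.71), Prelp (-2.38 ± 0.36) and Klk10 (-2.30 ± 0.27). Single passages had 243 genes at least 2-fold higher and 328 lower (passage 1) and 276 higher and 215 lower (passage 3) than parental.

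Interferon response genes were higher in the liver sub-line than in parental cells for 19 of 20 members, with a median of 0.99, above all 10000 random lists. Ifit3 had 2.19 ± 0.56, Ifit1 1.77 ± 1.03 and Oasl2 1.74 ± 0.88. Limma called 0 of the list over all genes and 0 adjusted over the list alone (4 at an unadjusted p under 0.05). Macrophage markers were higher with them, with a median of 1.05, above all random lists, and their median was 0.15 without liver passage 1. Of their 15 members 0 passed over all genes (3 at an unadjusted p under 0.05). Cd68 (1.47 ± 0.25), Csf1r (1.32 ± 0.26, with a lowest probe set of 0.06) and Fcgr3 (1.15 ± 0.25) passed adjusted over the list alone. Antigen presentation genes had a median of 0.58 (16 members, above all random lists), with 0 past the threshold over all genes (6 at an unadjusted p under 0.05). Adjusted over the list alone 5 were higher, Psmb8 (2.53 ± 0.28), Psmb9 (2.01 ± 0.38), Tapbp (1.12 ± 0.25), Psmb10 (1.11 ± 0.29) and Cd274 (0.91 ± 0.25). Chemokines had a median of 0.11 (16 members, percentile 87.4; -0.050 in liver passage 1 and 0.34 in liver passage 3), with 0 past the threshold over all genes (9 at an unadjusted p under 0.05). Adjusted over the list alone 5 were higher, with Cxcl2 (1.54 ± 0.43) and Cxcl10 (1.49 ± 0.48), and 2 were lower, Cxcl5 and Cxcl12 (-1.36 ± 0.25). The list of osteoclast-activating factors and their inhibitors had a median of -0.48 (12 members, percentile 0.01), with 0 past the threshold over all genes (5 at an unadjusted p under 0.05). Of its members 3 passed adjusted over the list alone, with the inhibitor gene Tnfrsf11b higher (2.20 ± 0.35).

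Hypoxia genes were lower in the liver sub-line than in parental cells for 15 of 19 members (median -0.34, below all random lists), with 0 past the threshold over all genes (5 at an unadjusted p under 0.05). Car9 (-1.74 ± 0.24), P4ha2 (-1.44 ± 0.22) and Egln3 (-1.30 ± 0.33) passed adjusted over the list alone. Cell cycle genes were lower for 23 of 27 members (median -0.36, below all random lists), but their median was -0.043 without liver passage 1 and -0.69 without liver passage 3. Limma called 0 of these over all genes and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05. The inflammatory list had a median of -0.37 (14 members, percentile 0.01) and included the interleukin 1 receptor antagonist Il1rn (-1.82 ± 0.48). Matrix proteases had a median of 0.27 (22 members, percentile 99.99) and the bone-metastasis signature of 0.47 (6 members, percentile 99.5). In these 3 lists limma called 0 over all genes and 0 adjusted over the list alone, with 2, 3 and 1 at an unadjusted p under 0.05. Without liver passage 3 the protease median was 0.17 and that of the bone-metastasis signature 0.23. Luminal genes had a median of -0.28 (13 members, percentile 0.63), with 0 past the threshold over all genes (5 at an unadjusted p under 0.05). Csn1s1 (-1.38 ± 0.22), Csn3 (-0.97 ± 0.21) and Esr1 (1.91 ± 0.34, with 1 probe set of opposite sign at -0.23) passed adjusted over the list alone. Alpl (-1.79 ± 0.25), Cldn2, Gpx2 (-1.93 ± 0.33), Cxcl12 and Mgp (-2.15 ± 0.61) passed only when adjusted over the list alone, in the bone matrix, claudin, NRF2 and, for the last 2, fibroblast lists. The 8 hepatocyte markers had a median of 0.08 (percentile 75.2), which was 0.26 without liver passage 1 and -0.055 without liver passage 3, with 0 called over all genes, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. Over all genes, limma called 0 members in each of the 37 lists, with 71 of 497 entries at an unadjusted p under 0.05.

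**Figure D2:**
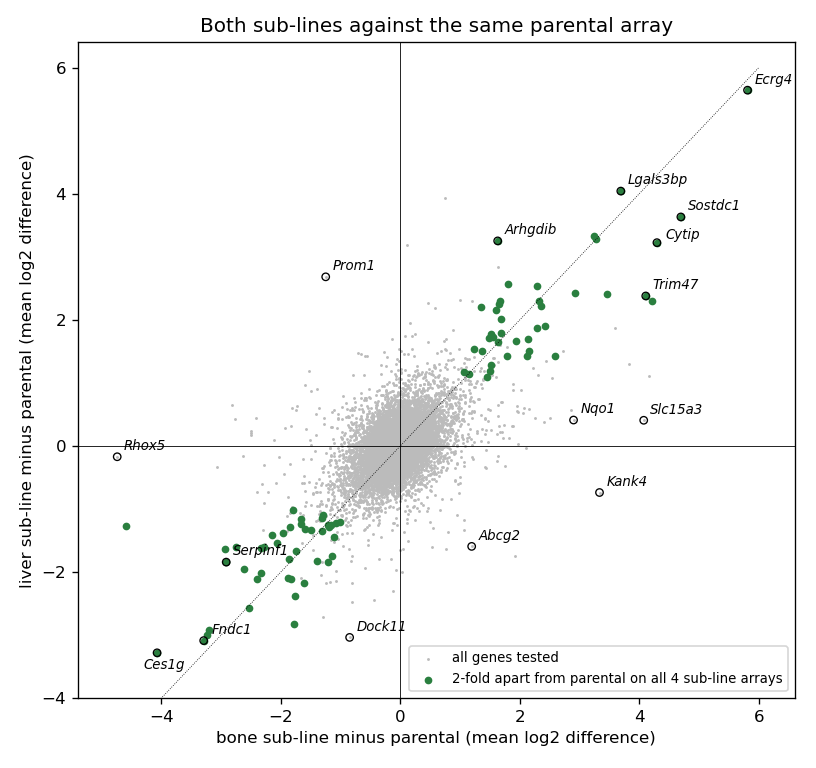
Mean log2 difference from the single parental array for the bone sub-line (horizontal) and the liver sub-line (vertical), 1 point per gene tested, with genes at least 2-fold from parental in the same direction on all 4 sub-line arrays in green and the line of equal difference dotted. Ecrg4 lies at 5.81 and 5.64, Slc15a3 at 4.07 and 0.41, Rhox5 at -4.74 and -0.17, and Abcg2 at 1.19 and -1.59.

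All 4 sub-line arrays were at least 2-fold above the parental array for 40 genes and below it for 42. Besides Ecrg4 and Sostdc1 the higher genes included Lgals3bp, Cytip, Aspa, Sema3b, Trim47, Psmb8, Psmb9, Esr1, Tnfrsf11b and Wnt10a, and the lower ones Cxcl5, Fndc1, Fxyd6, Ces1g, Serpinf1, Il1rn, Car9, Cxcl12 and Csn1s1. Xist, the RNA of X inactivation, had 225 in parental cells and 20.8 to 48.6 in the sub-lines (-2.40 ± 0.34 in bone, adjusted p = 0.0891; -2.12 ± 0.34 in liver, adjusted p = 0.194). Unchanged lines simulated against a common parental array gave 13.7 genes in each direction, and independent lists would share 1.08 higher and 1.36 lower genes. The correlation of the differences across genes was 0.517 against 0.667 simulated, and their covariance was 0.100 against 0.0845. There is 1 parental array, so it could not be divided, and part of the excess may come from it. In opposite directions, 1 gene, Abcg2, was 2-fold higher in both bone passages and 2-fold lower in both liver passages, and 0 genes were the reverse. Independent lists would share 1.19 and 1.23 such genes, so these counts are no higher than that.

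Final passages were set against early ones as values, with 1 array each and no replicate check. From bone passage 3 to passage 6, 45 genes were at least 2-fold higher and 261 lower, or 71 and 218 after quantile normalization. The actin-binding protein gene Marcks went from 332 to 0.4 (log2 difference -4.41, and -1.51 for the smallest of its 6 probe sets), and Igfbp3, which binds insulin-like growth factors, from 459 to 7.6 (-4.33). Them5 (-3.53), Rtp4 (-3.12) and the interferon-induced gene Usp18 (-3.06) were next, and Dynap (3.47), S100a4 (2.21) and Padi1 (1.77) were highest, with 2 genes known only by predicted or clone names among the 5 largest. The interferon response list had a median of -1.20, below all random lists, with 13 of 20 members at least 2-fold lower. Its median was 0.78 above parental at passage 3 and -0.67 at passage 6, where 16 of 20 members were lower than on all 4 other arrays. Claudins (-0.64) and immediate early genes (-0.40) were below all random lists, Wnt and BMP genes (-0.42) were at percentile 0.13, and cell cycle genes (0.56) were above all random lists. Cldn2 (-1.39), Egr2 (-2.12) and the ribonucleotide reductase subunit Rrm2 (0.93) had the largest differences among the claudins, immediate early genes and cell cycle genes, and were chosen after their values were seen. The claudins did not move together, with 6 of 10 lower and 4 higher. Cldn4, chosen in the same way, went from 1306 to 2176 (0.73).

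From liver passage 1 to passage 3, 212 genes were at least 2-fold higher and 142 lower. Lce1h (3.45), the muscle ankyrin-repeat gene Ankrd1 (2.51, from 602 to 3496), Sbspon (2.29), the arginase Arg1 (2.15) and Mcam (2.02) were highest, and the lysozyme gene Lyz1 (-3.00, from 117 to 0.6), Zfas1 (-2.83), Snhg12 (-2.62), the cathepsin Ctsc (-2.48) and the stress-induced pseudokinase Trib3 (-2.21) were lowest. Cell cycle (median 0.63), cholesterol synthesis (0.61), fatty acid synthesis (0.47) and interferon response genes (0.49) lay above all random lists, and p53 targets (0.44) were at percentile 99.99. Unfolded protein and amino acid stress genes (-0.65), immediate early genes (-0.32) and macrophage markers (-0.89) lay below all random lists, and inflammatory genes (-0.37) were at percentile 0.01. Examples chosen after their values were seen are Idi1 (1.52) of cholesterol synthesis, Rrm2 (1.36) of the cell cycle, Chac1 (-1.53) of the stress genes, and C1qa (-2.08) and Ctss (-2.01) of the macrophage markers. The SD of a difference between passages of a sub-line was 0.406 over genes.

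**Figure D3:**
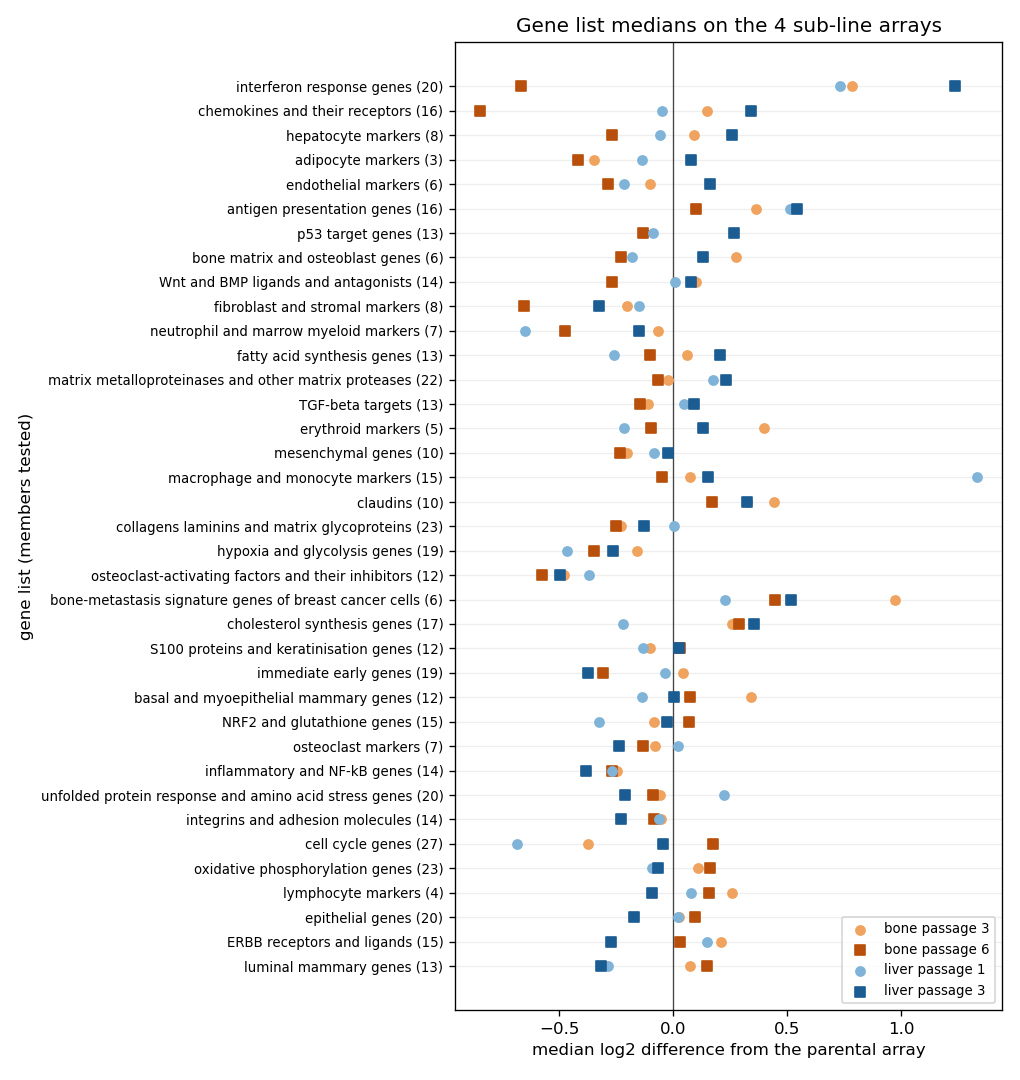
Median log2 difference from the parental array (horizontal) for each gene list (vertical), with 1 point per sub-line array. Interferon response genes lie at 0.78, -0.67, 0.73 and 1.24 and macrophage markers at 0.07, -0.05, 1.33 and 0.15 in bone passages 3 and 6 and liver passages 1 and 3.

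**Figure D4:**
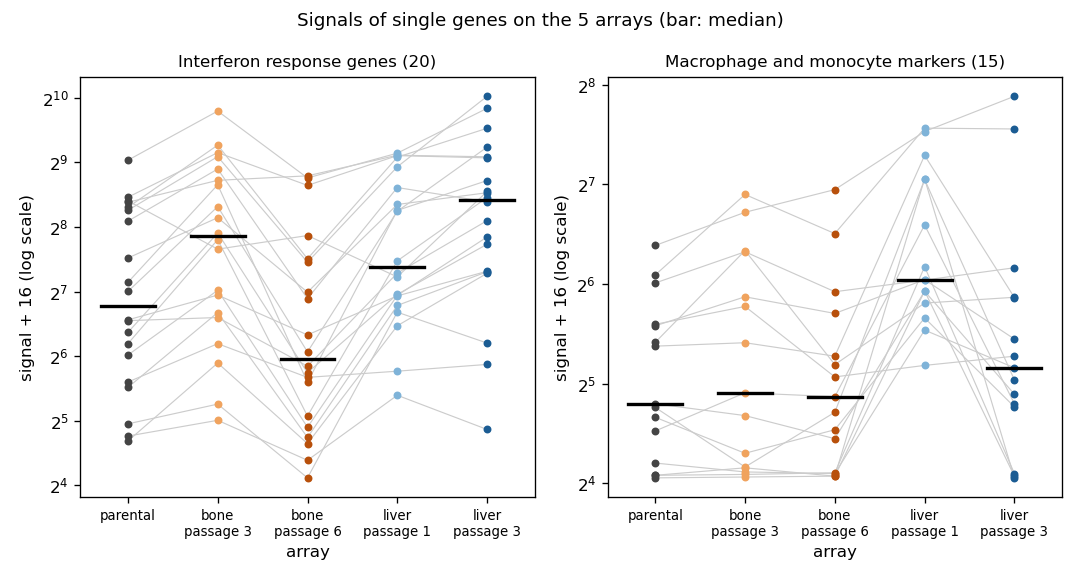
Each tested member of the interferon response list and of the macrophage list, 1 line per gene, over the 5 arrays in log2(intensity + 16). Usp18 has 387 in bone passage 3 and 32.3 in bone passage 6, and Lyz1 has 117 in liver passage 1 and 0.8 or less on the other arrays.

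Genes known for roles in bone metastasis were given whatever their values. Csf1 had 492 and 491 in the bone sub-line, 1400 and 1044 in the liver sub-line and 709 in parental cells, and the Notch ligand Jag1 had 362 and 425 in bone, 1452 and 752 in liver and 677 in parental cells. The osteoprotegerin gene Tnfrsf11b was at 4.2 in parental cells, 47.9 and 25.6 in bone and 61.8 and 95.2 in liver (bone against liver -0.85 ± 0.29, adjusted p = 0.276). The chemokine receptor Cxcr4 reached 27.5 at most (0.61 ± 0.29 between bone and liver) and Ccn2, formerly Ctgf, 31.3 (0.87 ± 0.31), both close to the lower limit of the filter. Tnfsf11 (RANKL), Ibsp, Il11 and Dkk1 had highest intensities of 5.6, 16.2, 12 and 15.3 and were left out by the filter, and Pthlh, Spp1 and Runx2 are not named in the annotation used here. Erbb2 had 312 in parental cells, 342 and 319.5 in bone and 212 and 280 in liver (bone against liver 0.42 ± 0.21). Whether the probe set named Erbb2 reads the neu oncogene of these cells was not checked, so these values need not give its level. The epithelial cadherin Cdh1 lay between 3282 and 3724 on all 5 arrays, with differences of 0.01 ± 0.22 for bone and 0.13 ± 0.22 for liver against parental, the former of opposite sign (-0.012) after quantile normalization. Vim, the mesenchymal intermediate filament, had 5740 in parental cells, 3525 and 1818 in bone and 4553 and 4769 in liver (bone against parental -1.18 ± 0.39, adjusted p = 0.482). Epithelial genes (20 members) had a median of 0.06 and mesenchymal genes (10 members) of -0.26 between bone and liver. The epithelial median was 0.20 without liver passage 1, 0.10 without bone passage 3, 0.029 without bone passage 6 and 0.0091 without liver passage 3. Limma called 0 of either list over all genes or adjusted over the list alone, with 2 and 2 at an unadjusted p under 0.05.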

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

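The test on macrophage markers in the bone passages, the counts of interferon genes lower in bone passage 6, the count of macrophage markers standing out in liver passage 1 and the test on hepatocyte genes were chosen after the results were seen, as were the values without liver passage 1 or bone passage 6; the other tests had been written before.

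Abcg2 was 1.19 ± 0.24 above parental in the bone sub-line and -1.59 ± 0.24 in the liver sub-line on the log2 scale, with both passages of each moving the same way. The difference between these values was not tested as an interaction; because both share the parental array, it equals the contrast of bone against liver, 2.79 ± 0.19 (limma adjusted p = 0.0342).

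Interferon response genes were lower in bone passage 6 than in bone passage 3, with a list median of -1.20. Scaling or a dim background of the passage 6 array would leave little after quantile normalization among brighter genes, but the 13 members with a mean intensity of at least 100 then had a median of -1.58. More macrophages in passage 3 would lower macrophage markers by as much, but their 15 members had a median of -0.083, or 0.01 after quantile normalization, and Lyz2 had 26.5 and 22.7 in passages 3 and 6. A rise in passage 3 alone would leave passage 6 near parental, but 17 of 20 members were lower there than in parental cells and 16 of 20 lower than on all 4 other arrays, with a median of -0.67 against parental, while passage 3 (0.78) lay close to liver passage 1 (0.73). A candidate explanation, as a hypothesis, is that interferon signalling was lower in passage 6; whether culture, handling or the sub-line itself lowered it was not tested and stays open with 1 array per passage.

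Macrophage markers were higher in liver passage 1 than on the other arrays. Noise of dim probe sets would put few members far out. However, 7 of 15 were at least 2-fold above all 4 other arrays, against 1 at the 99th percentile of random lists. Carry-over of liver parenchyma would raise hepatocyte genes, but the 8 tested had a median of -0.18 against 1.14 for the macrophage list. Of these 8, 5 were already at or above the median of all values in parental cells, which limits this test. Alb and Apoa1, below the filter and not among the 8, had 4.8 and 15.6, against 15.8 and 16.4 in parental cells. Apoa2 had 16. Ttr (17 against 0.7 to 4.2 on the other arrays), Fgb (2.6) and Ahsg (2.9), also below the filter, were highest in liver passage 1. A small carry-over is therefore not excluded. Residual host macrophages may be the source, as a hypothesis. Of a second macrophage list, 1 of 13 members, Ccl6, stood out by 2-fold, which is no more than the 1 that chance allows. Its other members, except Fcna, Folr2, Ms4a6d and Spi1, were also highest in liver passage 1, by less than 2-fold on the log2 scale used. Among them were Cd52 (31.6 against 10.7 or less), Ncf4 (25.7 against 9.6 or less) and Cfp (32.9 against 32.4 or less). The source stays open. Within the first list, the highest intensities in liver passage 1 were those of Cd68 (173), Csf1r (169), Lyz2 (140), Lyz1 (117) and Ctss (116). Cd68 (172) and Csf1r (220) were as high or higher in liver passage 3. Of the 15 markers, 7 had a parental intensity at or above the median of all values and 1, Ctss, is on another list.

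The parental array stood at least 2-fold apart from all 4 sub-line arrays for 82 genes, against 66 for the next array, liver passage 1. Noise of a lone array and selection of the sub-lines cannot be told apart from this count, since each passage was measured on 1 array. For a sub-line array, the 4 others include the other passage of its own line, whereas the parental array has no such partner. This alone favours a higher parental count. Dim probe sets may add to it, as 31.7% of the 82 genes had a highest intensity under 100, and with those left out the counts were 56 and 51. Selection of the sub-lines for bone or liver stays an untested explanation.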

How the results depend on the processing

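Pseudocounts of 1 and 32, the minimum intensity of 100, the counts without liver passage 1 or bone passage 6 and the list medians without each sub-line array were chosen after seeing the data. No paired analysis by replicate number was possible because the labels give none that pair the samples. The early or final stage served as a block instead, with fewer residual degrees of freedom than the main fit. It joins bone passage 3 with liver passage 1 and bone passage 6 with liver passage 3, which are different passages. Pearson's r was 0.957 and 0.965 within these pairs and 0.962 and 0.953 across them, so they show no clear pairing. The limma counts, 24 for bone against liver, 17 for bone against parental and 2 for liver against parental, depended on the setting. In that order, no filter gave 0, 1 and 1, and a pseudocount of 1 also gave 0, 1 and 1. The test against a 1.5-fold change gave 1, 6 and 1, median centring gave 54, 36 and 4, and a trend gave 52, 31 and 7. Bone against liver gave 39 with the filter on the mean, 54 with a pseudocount of 32, 37 with an intensity of at least 100, 15 with averaged probe sets and 161, holding all 24, with the stage as a block. Bone against parental gave 9 with averaged probe sets, and liver against parental 4 with all probe sets, 9 with a pseudocount of 32 and 4 with an intensity of at least 100. Without the other sub-line the parental comparisons gave 8 (bone) and 38 (liver). Leaving out only 1 array of the other sub-line gives the same fit. Leaving out each sub-line array in turn gave 0 to 75, 8 to 52 and 0 to 38; a lone passage is then assumed to vary as the other line's passages do. Quantile normalization (26, 24 and 3) and the robust prior (28, 18 and 3) kept all 3 counts within 1.5 times. Beside the 0 calls of limma, 2154 (no filter) and 1581 (pseudocount of 1) genes had an unadjusted p under 0.05. The cause was not tested.

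Apart from fits with 1 array left out, Ecrg4 was called in all 13 alternatives in both parental comparisons, Sostdc1 in 11 (bone) and 10 (liver) of 13, and Slc15a3 in 12 of 14 between bone and liver. Called values of named genes kept their side of the threshold in 392 alternatives and lost it in 133, with 87 and 69 when 1 array was left out. Values not called kept theirs in 1307 and passed in 77. Of the named genes only Cdh1 changed sign, for bone against parental, to -0.012 after quantile normalization from 0.01, and between -0.036 and 0.061 when 1 array was left out. List medians moved by more than the spread in 195 of the alternatives and by less in 654, and some medians near 0 changed sign. Without bone passage 3, the median of the bone-metastasis signature between bone and liver went from 0.46 to -0.022, and that of cell cycle genes between bone and parental from -0.14 to 0.17.

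Counts of genes 2-fold apart are given for bone passages 3 and 6 and liver passages 1 and 3 against parental, early and final bone against liver, and final against early bone and liver. At 3-fold they were 168, 169, 116, 127, 170, 149, 62 and 58. A pseudocount of 1 gave 1030, 1118, 1089, 907, 1266, 1168, 815 and 791, and a pseudocount of 32 gave 342, 349, 346, 303, 468, 348, 159 and 207. An intensity of at least 100 gave 324, 327, 366 and 313 against parental, 365 for final bone against liver, and 161 and 224 for the passages; fewer genes are tested then. In every pair of bone against liver, bone against parental and liver against parental, there were 36, 91 and 59 at 3-fold and 246, 528 and 456 with a pseudocount of 1. Against parental there were 175 and 140 with a pseudocount of 32, and 169 for bone with an intensity of at least 100. With fewer pairs, there were 259 (bone against liver) and 491 (liver against parental) without liver passage 1, and 309 (bone against liver) and 550 (bone against parental) without bone passage 6. A count over every pair cannot fall when pairs are dropped, so these rises do not measure dependence on an array. Signals near background limit what dim genes can show, since a small pseudocount magnifies their differences.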

Other observations

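No test in this part was run beyond those of the report; the genes named here and the medians without 1 array were chosen after the values were seen. The genes of this paragraph are among those at least 2-fold apart from the parental array on all 4 sub-line arrays. The secreted protease inhibitor gene Slpi had 1640 in parental cells and 3327 to 4720 in the sub-lines (1.44 in bone and 1.09 in liver on the log2 scale). The granulocyte growth factor gene Csf3 had 2027 in parental cells and 428 to 652 in the sub-lines (-1.88 and -2.10), and Cxcl5, another product that acts on neutrophils, had 1233 against 112 to 164. The actin-bundling gene Lcp1 had 1101 against 201 to 439 (-1.83 and -2.12), and the collectin gene Sftpd had 311 against 23.7 to 60.3 (-2.53 and -2.57). Mesothelin, Msln, had 77.2 in parental cells and 209 to 594 in the sub-lines (2.13 and 1.70). Of these genes limma called Cxcl5 between bone and parental, and called none of the others in either parental comparison.

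In liver passage 1 the small nucleolar RNA host genes Zfas1 and Snhg12 stood at 3524 and 798, against 482 to 961 and 91.6 to 241 on the other arrays. The stress genes Trib3, at 1923 against 385 to 1109.5, and Chac1, at 1539.9 against 386 to 997, were highest there as well, and of the 20 members of their list 15 were lower and 5 higher in passage 3 than in passage 1. The cholesterol synthesis gene Idi1 was lowest there, at 127 against 333 to 541, as was the cell cycle gene Rrm2, at 992 against 1544 to 2949.

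Further lists had 0 members called by limma over all genes and 0 adjusted over the list alone between bone and liver, and their medians moved when 1 array was left out. Between bone and liver the medians were 0.17 for cell cycle genes (1 of 27 members at an unadjusted p under 0.05, 22 of 27 higher), 0.14 for cholesterol synthesis genes (1 of 17), 0.12 for S100 and keratinisation genes (1 of 12), -0.12 for p53 targets (1 of 13) and -0.19 for TGF-beta targets (4 of 13, with a mean of 0.0027). In this order they were 0.48, 0.25, 0.048, -0.33 and -0.088 without bone passage 3, and -0.031, 0.23, -0.019, -0.20 and -0.25 without bone passage 6. Without liver passage 1 they were -0.076, -0.034, -0.042, -0.28 and -0.27, and without liver passage 3 they were 0.50, 0.51, 0.27, 0.11 and 0.032. At passage 3, which both sub-lines share, the cell cycle median against parental was -0.37 in bone and -0.043 in liver. Among markers of other cell types, the medians between bone and liver were 0.05 for neutrophil, 0.07 for lymphocyte, 0.19 for erythroid and 0.02 for osteoclast markers, with 0, 1, 0 and 1 members at an unadjusted p under 0.05. For these 4 lists the values were 0.22, 0.040, 0.042 and -0.036 without bone passage 3, and 0.15, 0.12, 0.33 and 0.14 without bone passage 6. They were -0.079, 0.30, 0.016 and 0.17 without liver passage 1, and 0.21, -0.15, 0.26 and 0.11 without liver passage 3.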
